A study of Mus musculus with 4 samples.

How the data were processed

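Melanomas grown from the mouse line YUMM5.2 were dissociated to single cells, labelled with cell multiplexing oligos (CMOs, short lipid-anchored DNA tags that can mark which tumor a cell came from) and loaded on a 10x Genomics droplet system that captures polyadenylated RNA from the 3′ end. Per the labels, 4 libraries were made: a gene-expression library and a CMO library for a pool of 6-hydroxydopamine (6-OHDA) and vehicle tumors, and the same pair for a pool of resiniferatoxin (RTX) and vehicle tumors. The series design gives 3 tumors per treatment arm, and each pool holds 2 arms. All 4 libraries carry the same lane label, so no batch within the series can be separated.

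The submitters' processing notes name Cell Ranger and the mouse assembly mm10; the Cell Ranger version and the gene annotation are not given in the sources used here. The 5 deposited files used here were the list of cell barcodes and the list of features for each gene-expression library, and a table with the identifier and sequence of each CMO. These lists hold names and sequences and carry no measured value beside any entry. The matrices that would pair a gene with a barcode and a number of molecules were not analysed here, nor were files of the CMO libraries. The file names of the barcode lists call them raw, and a raw list names barcodes in general and not called cells. No source used here says which CMO marked which tumor or which arm. For these reasons no drug arm was compared with its vehicle, no cell was assigned to a type, and no expression level, fold change or p-value is given. The planned test of summed counts per tumor and cell type could not be carried out on these files.

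From the lists, the following were computed with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. Barcodes were counted per library and matched between libraries as whole strings. Each shared share has an exact (Clopper-Pearson) 95% binomial interval, which covers counting error only. The number of barcodes in a pool from which both lists would be independent random draws was estimated as the product of the list lengths divided by the number shared. Base composition was counted by position from the first base of the barcode. Pairs of barcodes that differ at 1 position were counted within each list over all positions and exchanges. For the neighbour ratio, defined below, only exchanges of A with G or of C with T at positions 10 to 16 were counted. They were counted at 1 or at 2 positions, so other pairs with 2 mismatches were left out. The interval of the ratio is from a jackknife over 246 blocks of barcodes that begin with the same 4 bases. The pool estimate and the neighbour ratio were tested on simulated lists. With 4000000 barcodes simulated, the estimate came to 99.94% of that number, from which repeated barcodes had been removed before the draws. The neighbour ratio is the product over both lists of own to other neighbours. Before it was simulated, neighbours by such exchanges at positions 10 to 16 were added to the pool. For independent draws from that enlarged pool the neighbour ratio was 0.9951 at 1 mismatch and 0.9989 at 2. Read errors were then added to the simulated lists, only as the exchanges at positions 10 to 16 that the ratio counts. With them the ratio was 1.451 at 1 mismatch and 0.9769 at 2. A value above 1 at 1 mismatch was thus built into that simulation. Figures were drawn with matplotlib 3.10.9.

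Gene features were matched by Ensembl identifier to GENCODE mouse release M21, which annotates GRCm38, the assembly that mm10 names. Coordinates below are those of that release on GRCm38, counted from 1, and 32235 of the 32285 gene identifiers were found in it. A gene was called overlapped when its annotated span shared at least 1 base with the span of another listed gene. Genes are named from 6 gene lists and 14 lists of cell type markers that were fixed before the data were examined. Because no values were at hand, the rule for named genes allowed only a statement on whether a member is listed. Some members of the lists are not reported here by name. Each alternative in the closing section was also fixed beforehand, except where stated. Depth per cell is unknown, since the lists hold no counts of reads or molecules. Each pool has 1 gene-expression library, so a difference between the libraries has no replicate check.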

Results

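The series was designed to ask how cells of a mouse melanoma and its surroundings respond when sympathetic or sensory nerves are removed. 6-OHDA is a neurotoxin taken up by catecholaminergic nerve endings, and RTX is an agonist of the Trpv1 channel that ablates sensory neurons carrying it. Tumors of the 6-OHDA arm were pooled with tumors given its vehicle, ascorbic acid, and tumors of the RTX arm were pooled with tumors given its vehicle, DMSO. Each pool came from 6 tumors, 3 per arm, which makes 12 tumors in all. Loading aimed at about 15000 cells per pool. The data examined were the barcode list and the feature list of the gene-expression library of each pool, and the table of multiplexing tags. They contain no expression values, so neither drug could be compared with its vehicle, and what follows describes which genes and which barcodes the libraries were indexed by.

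The fixed lists of genes of adrenergic signalling, sensory nerves, immune state and cell types were complete among the features of both libraries. The feature lists were identical in every one of their 32297 entries, of which 32285 were genes and 12 were multiplexing tags. All 99 genes of the 20 fixed lists were present, 45 in the gene lists and 54 among the cell type markers. A listed gene is one that could be counted. Its presence in the list describes the gene annotation used for counting, not these tumors, and is no evidence of expression.

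All 9 adrenergic receptor genes were listed. They include Adrb1 (ENSMUSG00000035283, chromosome 19, 56722199 to 56733113, plus strand) and Adrb3 (ENSMUSG00000031489, chromosome 8, 27225776 to 27250616, minus strand), which encode receptors for noradrenaline and adrenaline. Adra1d and Adrb3 each overlap 1 listed gene on the opposite strand, Gm14285 and Gm45470 respectively, and the other 7 receptor genes overlap none. All 7 genes of catecholamine synthesis and transport were listed as well. Among them are Th (ENSMUSG00000000214, chromosome 7, 142892752 to 142931128, minus strand), the rate-limiting enzyme of catecholamine synthesis, and Slc6a2 (ENSMUSG00000055368, chromosome 8, 92960079 to 93001667, plus strand), the noradrenaline transporter. In this group Ddc overlaps 1700042O10Rik and Slc18a2 overlaps Gm29261, in each case on the opposite strand.

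The 7 sensory neuron and neuropeptide genes were listed and none overlaps another listed gene. Trpv1 (ENSMUSG00000005952), which encodes the receptor that RTX binds, spans 73234292 to 73261242 on the plus strand of chromosome 11. Calca (ENSMUSG00000030669, chromosome 7, 114631478 to 114636357, minus strand) encodes calcitonin and the neuropeptide CGRP, and Ramp1 (ENSMUSG00000034353, chromosome 1, 91179822 to 91225196, plus strand) encodes a subunit of the CGRP receptor.

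Genes of the immune lists were present in full. The interferon response list had 10 of 10 members, among them Ifng, Irf1 and Cxcl9. In that list Cxcl10, which encodes a T cell chemoattractant, overlaps Art3 on the opposite strand, and B2m, the light chain of class I MHC, overlaps Patl2. The T cell dysfunction list had 6 of 6 members, including the checkpoint receptor genes Pdcd1, Lag3 and Ctla4, and Tox overlaps Gm11802 on the opposite strand. The macrophage suppressive state list had 6 of 6 members, including Arg1 and Mrc1, with no overlaps.

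The cell type lists covered melanoma cells, T, NK and B cells, macrophages, dendritic cells, neutrophils, fibroblasts, endothelial cells, pericytes, Schwann cells, erythroid cells, keratinocytes and adipocytes. Of their 54 genes, 11 overlap another listed gene, in each case on the opposite strand. The pigment cell genes Pmel and Dct are in this group: Pmel overlaps Cdk2 and Dgka, and Dct overlaps 4930435M08Rik. The macrophage gene Csf1r overlaps Hmgxb3, and the Schwann cell gene S100b overlaps Dip2a. Over all lists, 19 of 99 genes overlap a listed gene on the opposite strand and 0 overlap one on the same strand. The share over all listed genes is not given here, so these counts cannot be called high or low. The strand setting of the counting is not given in the sources used here. The erythroid genes Hba-a1 and Hbb-bs have closely similar copies, Hba-a2 and Hbb-bt. A read that matches both copies cannot be placed on either from its sequence, and how such reads were counted was not examined.

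Of the 32285 listed genes, 32235 (99.85%) were found in GENCODE M21. Protein-coding genes numbered 21702, long noncoding RNA genes 9830, and immunoglobulin or T cell receptor segments 697. All 13 protein-coding genes of the mitochondrial genome were listed. Of 2207 annotated microRNA genes 0 were listed, and 9940 processed pseudogenes were left out against 1 listed. The lists hold 32245 distinct gene symbols, because 38 symbols are each used by more than 1 gene; 0 of the 99 genes of the fixed lists share a symbol.

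The tag table and both feature lists named the same 12 multiplexing tags, CMO301 to CMO312, for pools of 6 tumors each. The tags are 15 bases long and their GC content runs from 33.3% to 60%. Over the 66 pairs of tags, the number of mismatches had a median of 12, and the closest pair differed at 7 positions.

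The barcode list of the 6-OHDA pool held 1974182 barcodes and that of the RTX pool 1859887, so the former was 6.15% longer. Each barcode has 16 bases. These numbers come to 131.6 and 124 listed barcodes for each cell aimed for, and no cell call accompanies them. With 1 library per pool, the difference in length cannot be set against a spread between replicates, and each library mixes drug and vehicle cells. The lists shared 905832 barcodes, which is 48.7% of the shorter list (95% interval 48.63 to 48.78) and 45.88% of the longer one. Their union held 2928237 barcodes. Independent random draws would share this many from a pool of 4053462 barcodes (95% interval 4047490 to 4059451). The interval covers counting error only, and the estimate takes the draws to be independent and even across barcodes. In the 6-OHDA pool's list the shared percent rose from 41.2% at 5 G or C bases to 51% at 11. The draws were thus not even across barcodes, and the pool size holds only under that condition.

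**Figure D1:**
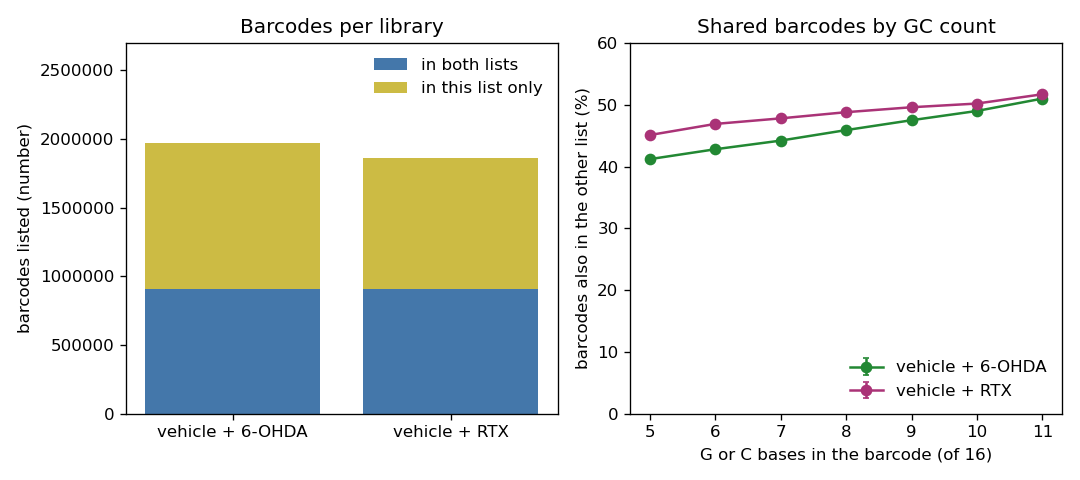
Left, number of barcodes listed for each gene-expression library (bars start at 0), split into those in both lists and those in 1 list only. Right, percent of each library's barcodes that are also in the other list, against the number of G or C bases in the barcode; error bars are exact 95% binomial intervals, mostly smaller than the points. The lists hold 1974182 and 1859887 barcodes, and the shared percent of the 6-OHDA pool's list goes from 41.2% at 5 G or C bases to 51% at 11.

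The lists had similar base composition. Over all positions and both libraries each base made up between 22.76% and 28.39% of barcodes, and the median absolute difference between libraries was 0.2 percentage points. The largest difference was at position 8, where C made up 26.11% of barcodes in the 6-OHDA pool and 24.29% in the RTX pool. Away from positions 8 and 9 the largest difference was at position 3, where C made up 25.69% of barcodes in the 6-OHDA pool and 26.21% in the RTX pool. Shared barcodes were more frequent among GC-rich barcodes. In the list of the 6-OHDA pool, 41.2% of barcodes with 5 G or C bases (95% interval 40.8 to 41.6) and 51% of those with 11 (50.6 to 51.3) were shared. The corresponding values in the list of the RTX pool were 45.1% (44.7 to 45.5) and 51.7% (51.3 to 52).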

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

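The share of barcodes found in both lists depends on its denominator: it was 48.7% of the shorter list, 45.88% of the longer list and 30.93% of the union. Removing the suffix changed nothing, since every barcode of both lists ends in the same one. The pool size for independent draws was 4071090 when only barcodes beginning with A were used and scaled up, which is 0.43% above the value from all barcodes and outside its counting interval; the cause was not tested. Summing the estimate over classes of GC count, an alternative chosen after seeing the data, gave 4058740, inside that interval. Matching features by symbol in place of identifier gave 32257 shared names against 32297, because some genes share a symbol. All 99 list genes were found whether or not case was heeded. The alternatives planned for the drug comparisons (DESeq2 size factors, no filter on low counts, leaving out each tumor) were not run, because the files used here hold no counts. Depth cannot be judged for the same reason, and every value comes from 1 library per pool.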

Other observations

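The test of read errors in this part was chosen after a first count of neighbouring barcodes had been seen; the test at 2 mismatches was fixed before its result was seen. Nothing here concerns the treatments, since each library mixes a drug arm with its vehicle.

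The bases at positions 8 and 9 of the barcode went together. Of 16 possible pairs, 4 occurred (AG, CA, GT and TC), and the same 4 in both libraries. Complementing both positions turns each of these pairs into another of them. In the 6-OHDA pool 12.5% of barcodes had their complemented partner in the same list and 12.7% had it in the other list, and in the RTX pool the values were 13.9% and 13.5%. The difference in base composition at position 8 is therefore the same difference as at position 9, with CA pairs at 26.11% and 24.29% of the lists.

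Barcodes that differ at a single position were found too, 67189 pairs in the list of the 6-OHDA pool and 84861 in the shorter list of the RTX pool. All of them differ at positions 10 to 16 by an exchange of A with G or of C with T. Per 100 barcodes found only in the 6-OHDA pool, there were 8.6 such neighbours in its own list and 7.81 in the other, an own-to-other ratio of 1.1; per 100 found only in the RTX pool, there were 12.1 and 9.94, a ratio of 1.22. The product of these 2 ratios, in which list length cancels, was 1.34 (95% jackknife interval 1.314 to 1.376). At 2 mismatches, with only such exchanges at positions 10 to 16 counted, the ratios were 1.09 (256 own and 235 other neighbours per 100) and 0.946 (232 and 245). Their product was 1.03 (1.027 to 1.034). Other barcodes with 2 mismatches, such as the partners complemented at positions 8 and 9, were not counted in it. From 2 mismatches to 1, the ratio hardly changed for the 6-OHDA pool (1.09 and 1.1). It rose for the RTX pool (0.946 and 1.22), so most of the difference between the products came from barcodes found only in the RTX pool. Read errors in frequent barcodes are a candidate source of neighbours in the own list. In both lists 0 pairs at 1 mismatch lay outside positions 10 to 16 or had another exchange. That argues against errors that add sequences of any kind to a list. Read errors could count only where they give a sequence of the kind listed. The product at 1 mismatch prompted the idea of read errors and is no test of it. That product was 1.31 times the product at 2 mismatches (1.275 to 1.336). Pools of beads differing on a fine scale would also give that order. Bead pools that differ by region of barcode sequence are a further candidate source, and the product of 1.03 at 2 mismatches is the excess they would need, at a small size. Simulated read errors gave a product of 0.9769 at 2 mismatches. That simulation used a pool of random sequences to which neighbours by such exchanges had been added. It put errors only at positions 10 to 16, in barcodes picked at random, not in frequent ones. Its value therefore cannot decide between the sources. Neither differing bead pools nor read errors that give a sequence of the kind listed are excluded, and read counts per barcode were not analysed here. No biological explanation was tested.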
